A study of Mus musculus with 50 samples.

How the data were processed

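RNA was measured in 50 libraries of mouse blood-forming cells: LSK and GMP sorted from WT mice at 4 weeks and from Flt3-mutant mice at 2, 4, 6 and 8 weeks (3 libraries per group), LSK and GMP of Npm1 Flt3 mice (4 each) and of Dnmt3a Flt3 mice (3 each), and lineage-negative progenitors of Npm1 Flt3 mice after 7 days of TAM or vehicle (3 each). Per the labels, the cells were sorted into Trizol, RNA was isolated with a column kit, and libraries were made with a paired-end or a single-end kit whose use by sample is not given. Per the submitters' processing notes, reads were aligned to mm10 with STAR and counted with featureCounts, with no version and no annotation stated. The deposited values are raw counts per gene, not normalised by the authors, for 33924 gene symbols in 2 tables, of 30 libraries (WT and Flt3) and 20 libraries (Npm1 Flt3 and Dnmt3a Flt3).

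Total counts lay between 306571 and 8249140 in the first table, with at least 10528 genes detected, except for Flt3 8-week GMP replicate 2 with 1942 counts over 988 genes, here called the near-empty library. It stayed in the edgeR fits, which weight it by its counts, and out of group means and figures. In the second table the totals lay between 15053600 and 128057000. A gene with no counts in a group was set against a floor of 3 counts over the group's summed total, and the fold is then a lower bound that covers counting error only. The 54 pairs of replicates were checked for copies of each other, and the lowest chi-square per degree of freedom was 2.35.

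All fits used R 4.3.3 with edgeR 4.0.16: low counts were filtered with filterByExpr on the groups in the fit, libraries were scaled with TMM, and genes were tested with the robust quasi-likelihood F test, with p adjusted by Benjamini-Hochberg over all genes tested and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. The p values measure the spread between libraries within groups, so they cover neither the difference between animals bred or sorted in different series nor the choice of time points. LSK and GMP of WT and Flt3 mice were fitted apart (15 libraries each), with the mean of the 4 Flt3 groups or the 4-week group set against WT, and the slope per week was fitted on the 12 Flt3 libraries. All 30 libraries were fitted together for LSK against GMP in WT and for the difference of the Flt3 effects. Npm1 Flt3 and Dnmt3a Flt3 were compared within LSK and within GMP, Npm1 Flt3 LSK and GMP in a fit of 12 sorted libraries, and TAM with vehicle in a fit of 6. Dnmt3a Flt3 LSK replicate 1 and GMP replicate 2 were left out, because their titles and the last letters of their sample codes name different cell types.

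The gene lists, 25 in number with 354 genes, were written before the data were examined, as were the comparisons. Of these genes 346 were found under their own symbol, 5 through a synonym and 3 not at all. Each list with 3 or more measured genes was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. Genes were named by a rule fixed at the same time: Flt3, Npm1 and Dnmt3a, the 8 largest rises and 8 largest falls past the threshold at a mean log2 CPM of 4 or more (without overlap between groups where a comparison has 2 groups), up to 4 members per list with the smallest p, and 8 marker genes of the sort in every sorted library. Predicted genes, clone names and sex-linked genes were passed over among the largest changes. The 4 sets of genes higher or lower in Flt3 LSK or GMP were tested with camera and fry in the TAM contrast, adjusted over the 4.

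Alternatives were the DESeq2 1.42.0 Wald test, median-ratio size factors in edgeR, no filter or one of 5 CPM on low counts, a block on the replicate number or on the animal number of the sample codes, other choices of groups in the fit, and leaving out each library in turn. Fits without the 2-week libraries or, for the slopes, the 8-week ones, without the near-empty library in DESeq2, TAM with library size alone, and list counts under such settings or with the 2 conflicting libraries back were added after the data were seen. Other splits of the samples into groups of the same sizes were fitted, all of them or up to 60 at random (30 for the difference between cell types). LSK and GMP libraries share an animal where their codes share a number, and for 14 pairs of WT and Flt3 libraries the correlation across genes of residuals within a pair lay between -0.0967 and 0.314. For 3 pairs of Npm1 Flt3 libraries it lay between 0.124 and 0.377. Title numbers were treated as numbers only, with correlations of 0.00551 to 0.146 in TAM and vehicle.

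The fits were tested on simulated data with 200 changed genes. A 4-fold change was recovered for 96% of genes in Flt3 GMP and 100% in Flt3 LSK. It was recovered for 52% and 31% in Npm1 against Dnmt3a GMP and LSK, and for 45% in TAM. In the same order, a 2-fold change was recovered for 74%, 83%, 13%, 6% and 3%, with 4.49%, 5.67%, 12.2%, 9.76% and 9.43% false calls. Simulated rises and falls were equal in number, unlike the changes in TAM, so scaling error there was not covered.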

Results

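The tables held counts per gene for 50 mouse libraries in 16 groups of marrow cells sorted as LSK (lineage-negative, Sca-1-positive, Kit-positive cells, which hold the stem cells) or as GMP (granulocyte-monocyte progenitors), or depleted of lineage-positive cells. Changes are log2 fold changes ± SE from edgeR's quasi-likelihood fit, and a gene rose or fell where its Benjamini-Hochberg adjusted p was under 0.05. WT libraries exist only at 4 weeks.

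The first contrast asked how the sorted populations of WT mice differ. Stem cell genes were higher in LSK and granule genes higher in GMP. Of 16 measured stem cell genes, 15 were higher in LSK (15 adjusted over the list alone, camera adjusted p = 8.12e-14 and 0.00015 with an estimated correlation). The transcription factor gene Hlf was higher by 3.40 ± 0.50 and Mllt3, a chromatin reader gene of stem cells, by 4.11 ± 0.58. All 12 measured primary granule genes were lower in LSK (12 adjusted over the list alone, camera adjusted p = 6.22e-40 and 0.000125 with an estimated correlation). Myeloperoxidase, Mpo, was lower by 3.91 ± 0.29, the acute-phase gene Hp by 4.27 ± 0.24 and neutrophil elastase, Elane, by 4.90 ± 0.40.

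Flt3, which encodes a receptor tyrosine kinase of early progenitors, was higher in WT LSK by 2.68 ± 0.19, and the cytokine signalling inhibitor gene Socs2 by 5.25 ± 0.40. The homeobox gene Meis1 was higher by 3.11 ± 0.28, and Dntt, the terminal transferase gene of lymphoid progenitors, by 6.32 ± 0.36. Lymphoid genes were higher for 5 of 7 measured members (5 adjusted over the list alone, camera adjusted p = 1.07e-07). STAT5 targets were higher for 8 of 13 (9 adjusted over the list alone, camera adjusted p = 3.47e-05). Mast cell, basophil and eosinophil genes were lower for 8 of 9 (8 adjusted over the list alone, camera adjusted p = 4.33e-07 and 0.0375 with an estimated correlation). Monocyte genes were lower for 7 of 15 (9 lower and 2 higher adjusted over the list alone), with camera adjusted p = 1.5e-05, but adjusted p = 0.112 with an estimated correlation. The monocyte surface gene Ly6c2 was lower by 5.10 ± 0.38. Interferon response genes were higher for 13 of 20 (14 adjusted over the list alone, camera adjusted p = 3.47e-05), with adjusted p = 0.199 with an estimated correlation. Mn1, a transcriptional coactivator gene, had no counts in the 3 WT GMP libraries and was at least 42.4-fold higher in LSK.

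Among all tested genes 3041 differed between WT LSK and WT GMP, 1655 higher in LSK and 1386 lower. Median-ratio size factors moved the median gene from 0.12 to 0.35 and the share of called genes that were higher to 75.8%, and every gene named here lies further from 0 than that. DESeq2, which also scales by median ratios, gave 0.35 and 75.8% with the near-empty library and 0.12 and 52.0% without it.

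The next contrast asked how Flt3-mutant GMP, taken at 2, 4, 6 and 8 weeks (12 libraries), differ from WT GMP (3 libraries). The sample codes of all Flt3 libraries share 1 prefix and those of all WT libraries another, so in every contrast of Flt3 with WT genotype and code series cannot be told apart. Flt3 itself was higher in the mutant cells by 2.40 ± 0.19 (adjusted p = 3.59e-14). Its level was 23.8 ± 6.14 CPM (mean ± SD, n = 3) in WT GMP and 136 ± 18.8 CPM in Flt3 GMP at 4 weeks. Genes of antigen presentation rose, and granule, erythroid and platelet genes fell. Of 11 measured genes that STAT5 is known to induce 5 rose (5 adjusted over the list alone, camera adjusted p = 4.67e-09 and 0.0175 with an estimated correlation). Socs2 rose by 8.13 ± 0.31, Cish, another inhibitor of cytokine signalling, by 5.23 ± 0.55, Socs1 by 2.09 ± 0.35 and the kinase gene Pim1 by 1.81 ± 0.39. Nov, which encodes the secreted matricellular protein CCN3, had no counts in the 3 WT GMP libraries and was at least 50.4-fold higher in Flt3 GMP.

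**Figure D1:**
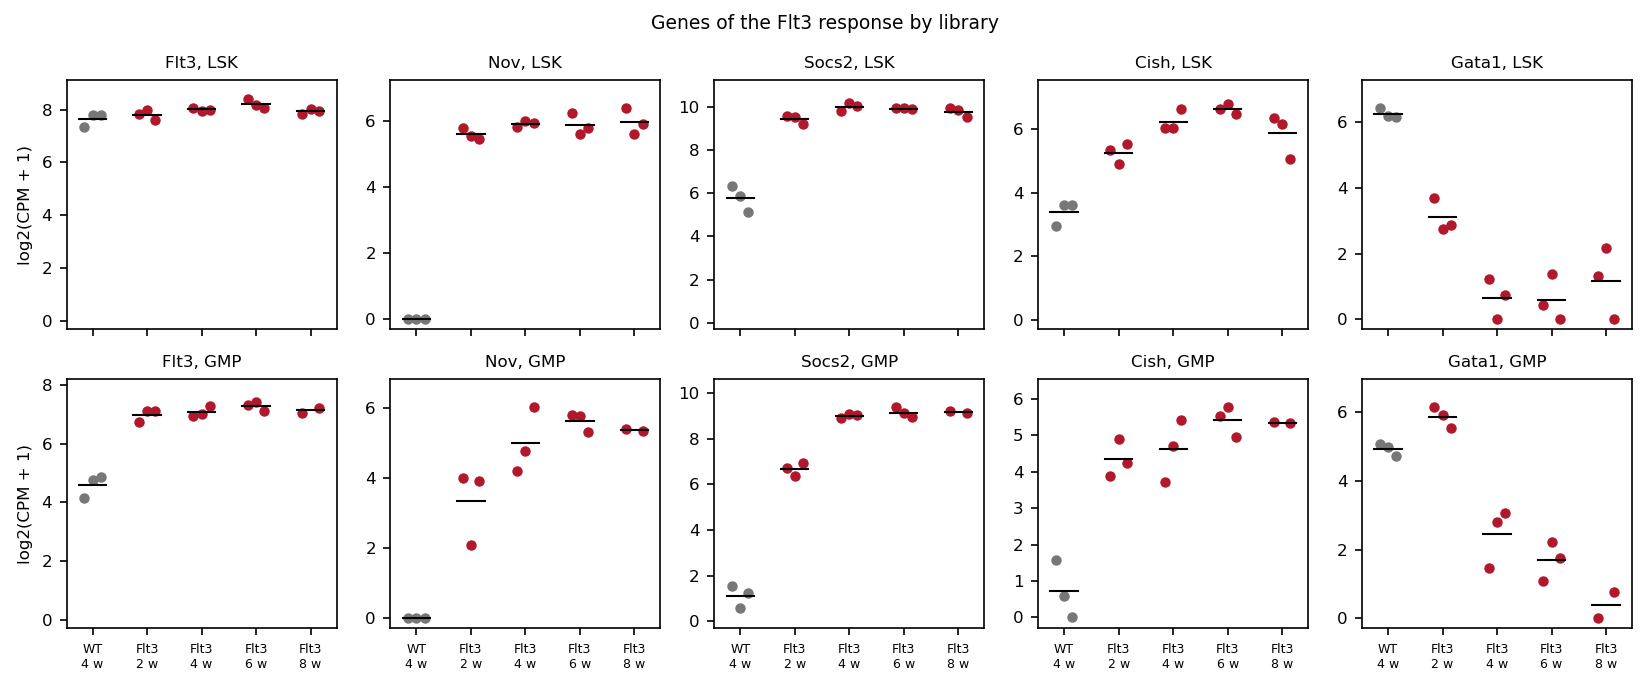
Each point is a library and each bar a group mean of log2(CPM + 1) for Flt3, Nov, Socs2, Cish and Gata1 in LSK (top) and GMP (bottom), in WT at 4 weeks and Flt3 at 2, 4, 6 and 8 weeks, with the near-empty Flt3 8-week GMP library left out. Socs2 lies above WT at every Flt3 time, and Nov is at 0 in all WT libraries.

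All 13 measured MHC class II and dendritic cell genes rose in Flt3 GMP (13 adjusted over the list alone, camera adjusted p = 3.89e-17 and 0.0408 with an estimated correlation). H2-Ab1, which encodes a chain of an MHC class II molecule, rose by 4.76 ± 0.39, H2-Aa by 5.74 ± 0.61 and Batf3, a transcription factor gene of dendritic cells, by 4.90 ± 0.52. Without the 2-week libraries all 10 then measured members rose. Among 14 monocyte genes 7 rose and 1 fell (8 and 2 adjusted over the list alone, camera adjusted p = 4.22e-06), with adjusted p = 0.0554 with an estimated correlation. Irf8, a transcription factor gene of monocytes and dendritic cells, rose by 2.29 ± 0.24, the lysosomal genes Psap and Ctss by 2.28 ± 0.19 and 2.10 ± 0.19, while Ly6c2 fell by 1.57 ± 0.17. Interferon response genes rose for 9 of 16 (10 adjusted over the list alone, camera adjusted p = 3.05e-05), with adjusted p = 0.158 with an estimated correlation. The phosphatase gene Dusp5 rose by 3.72 ± 0.29, and Plbd1 and Ifitm1 rose by 5.33 ± 0.56 and 3.37 ± 0.36.

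All 12 measured primary granule genes fell in Flt3 GMP (12 adjusted over the list alone, camera adjusted p = 9.32e-25 and 0.00693 with an estimated correlation). Ms4a3 fell by 2.23 ± 0.16, cathepsin G, Ctsg, by 1.82 ± 0.17 and Gfi1, a repressor gene needed for neutrophil formation, by 1.87 ± 0.18. Among 8 late neutrophil genes 4 fell and 2 rose (5 and 2 adjusted over the list alone, camera adjusted p = 6.37e-05 and 0.0436 with an estimated correlation). S100a8 and S100a9, which encode calprotectin, fell by 5.62 ± 0.30 and 4.58 ± 0.43. Erythroid genes fell for 5 of 6 (5 adjusted over the list alone, camera adjusted p = 1.28e-07 and 0.0175 with an estimated correlation). The red-cell carbonic anhydrase gene Car1 fell by 4.94 ± 0.33 and the erythroid transcription factor genes Gata1 and Klf1 by 2.87 ± 0.33 and 4.50 ± 0.53. At 2 weeks, though, Gata1 stood at 45.3 to 70.1 CPM in Flt3 GMP, above the 25.5 to 32.5 CPM of WT. Car1 and Klf1 overlapped with WT then (94.1 to 139 against 45.6 to 115 CPM, and 12.5 to 25.3 against 10.8 to 40.9 CPM). Megakaryocyte genes fell for 4 of 5 (5 adjusted over the list alone, camera adjusted p = 1.92e-05 and 0.0473 with an estimated correlation), with platelet factor 4, Pf4, lower by 3.76 ± 0.33. Gdf3, which encodes a TGF-beta family ligand, fell by 5.80 ± 0.30 and the myeloid receptor gene Trem3 by 3.37 ± 0.19. Mitochondrially encoded genes fell for 4 of 7 (4 adjusted over the list alone, camera adjusted p = 0.00349), with adjusted p = 0.193 with an estimated correlation. They held 0.450% to 0.459% of counts in WT GMP and 0.236% to 0.346% in Flt3 GMP, apart from the near-empty library and 8-week replicate 3 with 0.700%.

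Mast cell, basophil and eosinophil genes fell for 7 of 9 in Flt3 GMP and rose for 2 (7 and 2 adjusted over the list alone, camera adjusted p = 3.05e-05), with adjusted p = 0.0649 with an estimated correlation. The histamine-forming enzyme gene Hdc fell by 1.83 ± 0.14. Without the 2-week libraries all 9 fell. In the 3 Flt3 GMP libraries at 2 weeks the basophil protease genes Mcpt8 and Prss34, chosen after their values were seen, stood at 20700 to 22460 CPM and 31820 to 44440 CPM, against 405.1 to 532.1 CPM and 158.3 to 198.1 CPM in WT. In all, 2393 of 9122 tested genes differed between Flt3 and WT GMP, 1191 higher and 1202 lower. Without WT GMP replicate 1 the number was 1557. DESeq2 called 912 genes with the near-empty library and 2314 without it, and median-ratio size factors in edgeR moved the median gene from 0.04 to 0.17 and the share higher to 66.9%. In DESeq2, which also scales by median ratios, these were 0.17 and 71.2% with the near-empty library and 0.04 and 47.5% without it.

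Flt3 LSK at the same 4 times (12 libraries) were compared with WT LSK (3 libraries) to ask what the mutation changes in the fraction that holds the stem cells. Stem cell, erythroid and megakaryocyte genes fell, and of 13 STAT5 targets 5 rose and 1 fell. Flt3 rose by 0.47 ± 0.12 (adjusted p = 0.00465), but did not pass without WT LSK replicate 1 (adjusted p = 0.147). Of 16 measured stem cell genes 14 fell and 1 rose (15 and 1 adjusted over the list alone, camera adjusted p = 9.24e-28 and 0.00104 with an estimated correlation). Pdzk1ip1 fell by 4.09 ± 0.22, the adhesion molecule gene Esam by 3.65 ± 0.28 and the stem cell transcription factor gene Gata2 by 2.92 ± 0.20. Meis1 fell by 1.59 ± 0.14, in a list of 7 measured Hox and cofactor genes of which 3 fell (4 adjusted over the list alone, camera adjusted p = 0.00161), with adjusted p = 0.079 with an estimated correlation.

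Erythroid genes fell in Flt3 LSK for 8 of 9 and rose for 1 (8 and 1 adjusted over the list alone, camera adjusted p = 9.8e-26 and 0.000209 with an estimated correlation). Gata1 fell by 5.41 ± 0.31, Klf1 by 4.64 ± 0.33, Car1 by 5.74 ± 0.34 and the globin gene Hba-a1 by 3.86 ± 0.39. Megakaryocyte genes fell for 6 of 7 (7 adjusted over the list alone, camera adjusted p = 1.05e-21 and 0.00104 with an estimated correlation). The platelet integrin gene Itga2b fell by 4.21 ± 0.23, Pf4 by 5.47 ± 0.32 and Gp9 by 3.02 ± 0.25. Gdf3 fell by 6.93 ± 0.39. The iron exporter gene Slc40a1, the complement gene C1qc, the ficolin gene Fcna and the adhesion molecule gene Vcam1 fell by 6.40 ± 0.46, 5.56 ± 0.52, 6.17 ± 0.62 and 5.14 ± 0.52. Of 14 measured monocyte and macrophage genes 6 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.00134), with adjusted p = 0.341 with an estimated correlation. Of 9 measured MAPK feedback and early response genes 5 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.0231), with adjusted p = 0.15 with an estimated correlation. Mast cell, basophil and eosinophil genes fell for 6 of 8 (6 adjusted over the list alone, camera adjusted p = 0.000307) and stromal and endothelial genes for 2 of 3 (2 adjusted over the list alone, camera adjusted p = 0.00656), with adjusted p = 0.186 and 0.0549 with an estimated correlation. The ERK phosphatase gene Dusp6 fell by 2.23 ± 0.21 while Dusp5 rose by 2.45 ± 0.17.

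STAT5 targets rose in Flt3 LSK for 5 of 13 and fell for 1 (6 and 1 adjusted over the list alone, camera adjusted p = 2.58e-08 and 0.00276 with an estimated correlation). Socs2 rose by 4.09 ± 0.19, Cish by 2.94 ± 0.27 and the interleukin-2 receptor gene Il2ra by 4.90 ± 0.59. MHC class II and dendritic cell genes rose for 13 of 14 (13 adjusted over the list alone, camera adjusted p = 2.99e-13), with adjusted p = 0.0549 with an estimated correlation, and for 10 of 14 without the 2-week libraries. Xcr1 and Clec9a, receptor genes of cross-presenting dendritic cells, rose by 5.41 ± 0.73 and 4.32 ± 0.66, and Irf8 rose by 3.05 ± 0.30. The cell cycle inhibitor gene Cdkn1a rose by 2.68 ± 0.24. Against a floor of 3 counts over the 3 WT LSK libraries, where they had no counts, Nov was at least 119.9-fold higher, the glycine decarboxylase gene Gldc at least 71.4-fold and the dendritic cell lectin gene Cd209a at least 44.7-fold. In all, 1480 of 9892 tested genes differed, 682 higher and 798 lower.

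**Figure D2:**
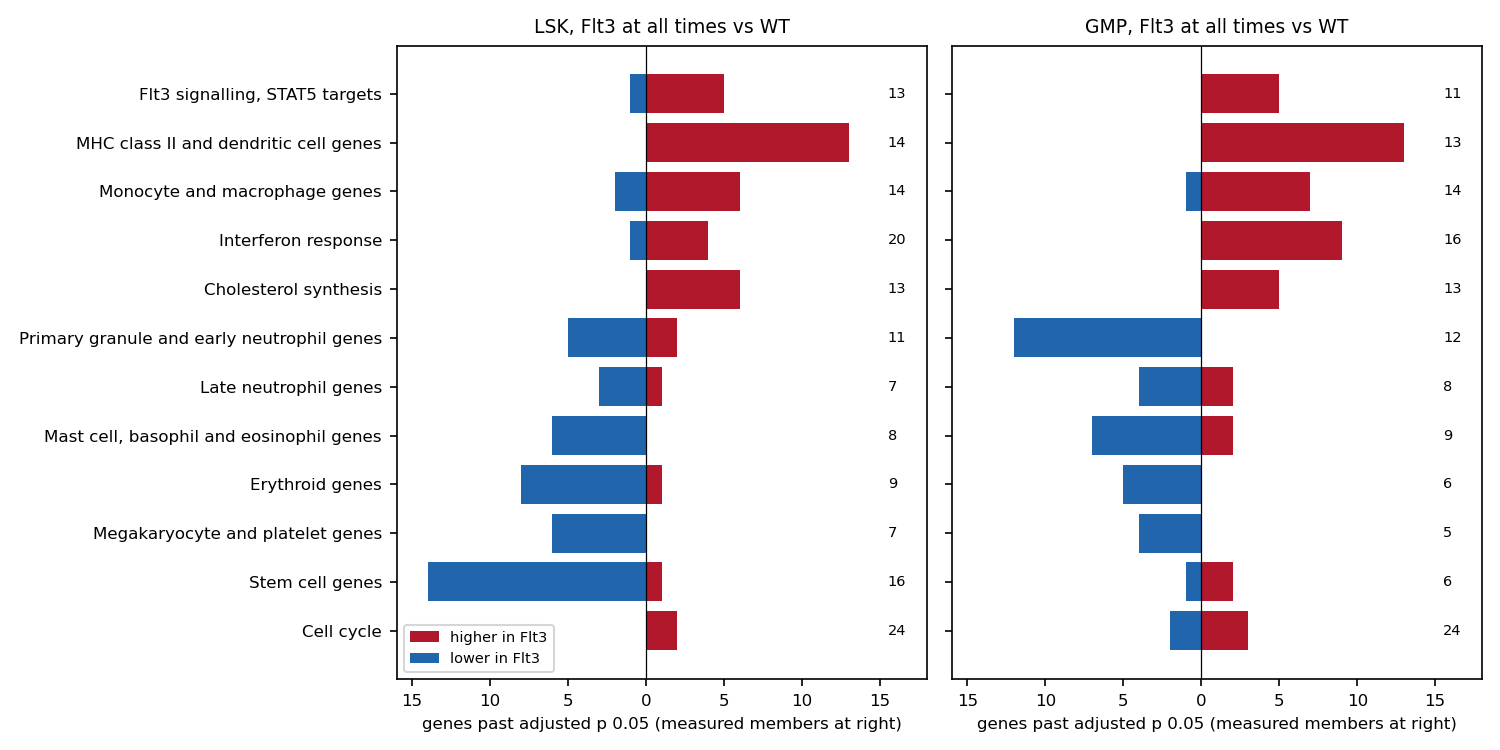
Bars give, for 12 of the gene lists, the number of genes higher (right of 0) and lower (left of 0) in Flt3 than in WT at adjusted p under 0.05, in LSK and in GMP, with the number of measured members at the right edge. In LSK 14 of 16 stem cell genes are lower, and in GMP 12 of 12 primary granule genes are lower.

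At 4 weeks alone, where both genotypes were sampled (3 libraries each), the same lists were counted. In GMP, Flt3 was higher by 2.28 ± 0.22 and Socs2 by 8.55 ± 0.33, and Nov was at least 54.2-fold higher. Primary granule genes fell for 9 of 12 (11 adjusted over the list alone, camera adjusted p = 9.84e-20 and 0.011 with an estimated correlation). Genes of MHC class II and dendritic cells rose for 11 of 13 (12 adjusted over the list alone, camera adjusted p = 2.75e-14 and 0.0312 with an estimated correlation), and erythroid genes fell for 5 of 6 (5 adjusted over the list alone, camera adjusted p = 4.61e-09). Monocyte genes rose for 8 of 14 and fell for 1 (8 and 1 adjusted over the list alone, camera adjusted p = 2.78e-07 and 0.0308 with an estimated correlation). Csf1r, the receptor gene for the macrophage growth factor, rose by 1.60 ± 0.21. Car1 had no counts in the 3 Flt3 GMP libraries at 4 weeks and was at least 63.9-fold lower. Mitochondrially encoded genes fell for 4 of 7 (5 adjusted over the list alone, camera adjusted p = 0.000109), with adjusted p = 0.13 with an estimated correlation. In all, 1364 genes differed in GMP, 655 higher and 709 lower. Median-ratio size factors moved the median gene from 0.04 to 0.16 and the share higher to 65.1%. In DESeq2, which also scales by median ratios, these were 0.17 and 66.9% with the near-empty library and 0.04 and 43.9% without it. The number was 770 without Flt3 4-week GMP replicate 3 and 889 without WT GMP replicate 1, and DESeq2 called 366 with the near-empty library in the fit and 1384 without it.

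In LSK at 4 weeks, stem cell genes fell for 13 of 16 (14 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.8e-22 and 0.00176 with an estimated correlation). Pdzk1ip1 fell by 4.97 ± 0.37 and Gata2 by 3.03 ± 0.30. Erythroid genes fell for 8 of 9 (8 adjusted over the list alone, camera adjusted p = 6.74e-22), with Klf1 lower by 7.63 ± 0.68. Megakaryocyte genes fell for 6 of 7 (7 adjusted over the list alone, camera adjusted p = 6.74e-16). STAT5 targets rose for 6 of 13 (6 adjusted over the list alone, camera adjusted p = 5.34e-09), Socs2 by 4.23 ± 0.21. MHC class II and dendritic cell genes rose for 7 of 14 (10 adjusted over the list alone, camera adjusted p = 7.52e-08), with adjusted p = 0.133 with an estimated correlation. Mast cell, basophil and eosinophil genes fell for 3 of 8 (6 adjusted over the list alone, camera adjusted p = 0.000362), with adjusted p = 0.181 with an estimated correlation. Flt3 was higher by 0.40 ± 0.14, which did not pass (adjusted p = 0.0703), and Nov was at least 124.9-fold higher. In all, 1003 genes differed, 449 higher and 554 lower.

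Whether the Flt3 effect differs between the sorted populations was tested as the effect in LSK minus the effect in GMP. As a log2 ratio, the effect on Flt3, Socs2 and Cish was smaller in LSK, and that on granule genes higher. In WT GMP Socs2 and Cish lay near the floor, at 0.498 to 1.97 and 0 to 1.97 CPM. In WT LSK they stood at 33.8 to 78.6 and 6.67 to 11.1 CPM. Their levels in Flt3 cells at 4 weeks were higher in LSK than in GMP. Socs2 stood at 910 to 1146 against 477 to 531 CPM, and Cish at 64.1 to 98.7 against 12.2 to 42.0 CPM. The difference of effects was -1.92 ± 0.21 for Flt3, -4.04 ± 0.45 for Socs2 and -2.31 ± 0.75 for Cish. Cish did not pass at 4 weeks alone (adjusted p = 0.162) or with DESeq2 (adjusted p = 0.0708). Nor did it without replicate 2 or 3 of WT GMP (adjusted p = 0.153 and 0.155) or of WT LSK (adjusted p = 0.0577 and 0.104). The difference was -2.90 ± 0.30 for Gata2, -3.73 ± 0.65 for Mllt3, -1.66 ± 0.32 for Meis1 and -2.70 ± 0.36 for Itga2b. Stem cell genes had a lower effect in LSK for 6 of 16 (6 adjusted over the list alone, camera adjusted p = 0.00193), with adjusted p = 0.0552 with an estimated correlation. Primary granule genes had a higher effect in LSK for 7 of 12 (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.48e-11 and 0.0464 with an estimated correlation), by 2.79 ± 0.21 for the protease inhibitor gene Cst7 and 2.21 ± 0.33 for Ctsg. S100a8, Ly6c2 and the chemokine receptor gene Ccr2 also had higher effects in LSK, by 3.34 ± 0.64, 2.10 ± 0.40 and 2.86 ± 0.63. At 4 weeks alone the difference for S100a8 was 2.59, which did not pass (adjusted p = 0.216). MAPK feedback and early response genes had a lower effect in LSK for 5 of 9 (6 adjusted over the list alone, camera adjusted p = 0.000347 and 0.0464 with an estimated correlation), Spry1, an inhibitor gene of receptor tyrosine kinase signalling, by 3.00 ± 0.76. Spry1 did not pass at 4 weeks alone (-3.10, adjusted p = 0.0686).

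The effect differed for 1278 of 10287 tested genes, 678 higher in LSK and 600 lower, and for 1517 with the animal number of the sample codes as a block. The number was 659 without WT GMP replicate 1, 845 without WT LSK replicate 3, and 424 at 4 weeks alone. DESeq2 called 649 with the near-empty library and 1445 without it. Median-ratio size factors moved the median gene from -0.10 to -0.27 and the share higher to 25.8%, and the genes named in this contrast lie further from 0 than that. In DESeq2, which also scales by median ratios, these were -0.29 and 23.1% with the near-empty library and -0.08 and 59.0% without it.

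The course of Flt3 libraries over 2, 4, 6 and 8 weeks was tested as a slope per week, within each sorted population. Flt3 showed a slope of -0.02 ± 0.03 in GMP and -0.01 ± 0.02 in LSK, neither of which passed. In GMP all 9 measured mast cell, basophil and eosinophil genes fell with time (9 adjusted over the list alone, camera adjusted p = 1.13e-12), with adjusted p = 0.202 with an estimated correlation. The IgE receptor gene Fcer1a fell by 2.47 ± 0.19 per week and Prss34 by 1.76 ± 0.29. Without the 2-week libraries the slope of Prss34 was -0.75, which did not pass (adjusted p = 0.307). The lipoxygenase genes Alox15 and Alox5 fell by 2.29 ± 0.23 and 1.65 ± 0.15 per week. NF-kB and inflammatory genes fell for 9 of 10 (10 adjusted over the list alone, camera adjusted p = 1.87e-08), with adjusted p = 0.202 with an estimated correlation. MHC class II and dendritic cell genes fell for 11 of 13 and rose for 1 (12 and 1 adjusted over the list alone, camera adjusted p = 1.08e-06), with adjusted p = 0.267 with an estimated correlation, and none of 10 passed without the 2-week libraries. Erythroid genes fell for 4 of 6 and rose for 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.00023), with adjusted p = 0.208 with an estimated correlation, Gata1 by 1.34 ± 0.10. Gata2 fell by 0.80 ± 0.10, the early response genes Fos and Egr1 by 1.02 ± 0.12 and 1.21 ± 0.15, and Socs2 rose by 0.31 ± 0.09 per week, which did not pass without the 2-week libraries (adjusted p = 0.956) or with the replicate number as a block (adjusted p = 0.0714).

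In LSK, the immunoglobulin genes Igkc, Igj and Ighm fell by 1.72 ± 0.38, 1.74 ± 0.39 and 0.64 ± 0.13 per week, and none of the 3 passed with the replicate number as a block (adjusted p = 0.0953, 0.0933 and 0.0862) or without any 1 of the 2-week libraries. Igkc stood at 18240 to 54920 CPM in the 2-week LSK libraries, 3.15 to 91.9 CPM at later times and 412 to 1244 CPM in WT. All 3 measured T and NK cell genes fell (3 adjusted over the list alone, camera adjusted p = 6.06e-07), with adjusted p = 0.0688 with an estimated correlation. Monocyte genes fell for 4 of 14 (12 adjusted over the list alone, camera adjusted p = 4.49e-10), with adjusted p = 0.251 with an estimated correlation. Mast cell, basophil and eosinophil genes fell for 2 of 6 (6 adjusted over the list alone, camera adjusted p = 2.53e-05), with adjusted p = 0.251 with an estimated correlation. Fos fell by 1.01 ± 0.12 and Egr1 by 0.92 ± 0.14. Without the 2-week libraries the slope of Egr1 was -0.18, which did not pass (adjusted p = 0.835). Fos stood at 1033 to 1334 CPM in LSK and 1073 to 1709 CPM in GMP at 2 weeks, against 26.1 to 135 CPM and 28.4 to 186 CPM later. The heat shock gene Hspa1a stood at 219 to 354.9 CPM and 424.7 to 637.8 CPM against at most 89.3 CPM and 121 CPM.

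**Figure D3:**
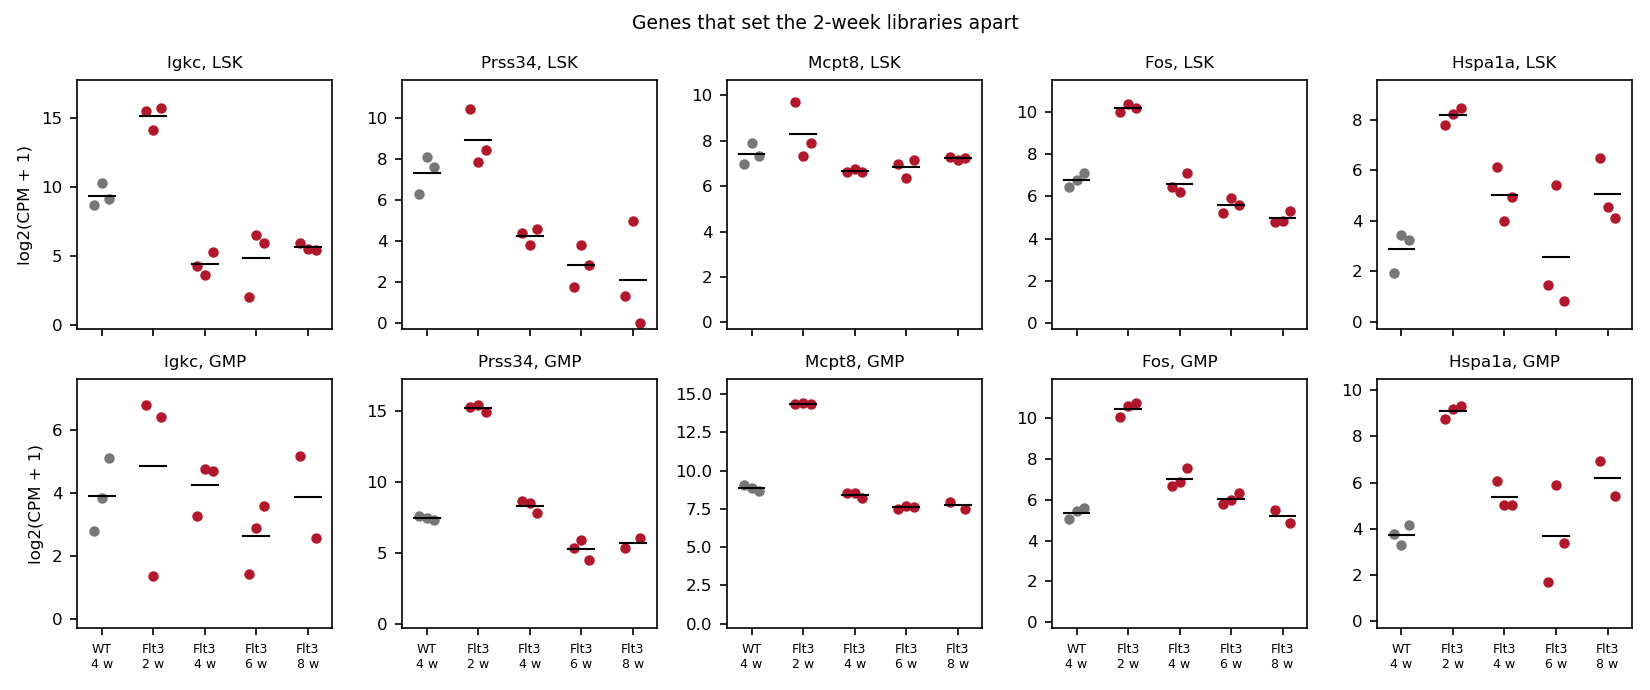
Each point is a library and each bar a group mean of log2(CPM + 1) for Igkc, Prss34, Mcpt8, Fos and Hspa1a in LSK (top) and GMP (bottom), in WT at 4 weeks and Flt3 at 2, 4, 6 and 8 weeks, with the near-empty library left out. The 2-week libraries lie above all later Flt3 libraries for Igkc in LSK, for Prss34 and Mcpt8 in GMP and for Fos and Hspa1a in both.

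The slope passed for 1075 of 8836 genes in GMP, 256 rising and 819 falling, and for 258 of 9556 in LSK, 69 rising and 189 falling. With no filter on low counts 1830 passed in GMP and 653 in LSK. In LSK the number was 442 with DESeq2, 120 with the replicate number as a block, 905 for 8 against 2 weeks, 995 for any difference among the 4 times and 673 without the 8-week libraries. Without the 2-week libraries 52 passed in GMP and 1 in LSK, and without 2-week replicate 1 or 3 in turn 613 or 611 in GMP. In LSK 75, 77 or 59 passed without 2-week replicate 1, 2 or 3, 505 or 396 without 4-week replicate 2 or 3, 170 without 6-week replicate 1 and 410 without 8-week replicate 3.

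Npm1-mutant, Flt3-mutant cells were compared with Dnmt3a-mutant, Flt3-mutant cells to ask how the second mutation goes with gene expression. In GMP (4 and 2 libraries) monocyte genes were far higher in Npm1 Flt3 cells. Flt3 was higher by 1.90 ± 0.30 (adjusted p = 0.00550), but did not pass without Dnmt3a Flt3 GMP replicate 3 (adjusted p = 0.0545). Of 16 measured monocyte genes 15 were higher (15 adjusted over the list alone, camera adjusted p = 8.93e-44 and 0.00275 with an estimated correlation), Ly86 by 7.28 ± 0.29, Ctss by 7.58 ± 0.41 and Ccr2 by 4.19 ± 0.21. MHC class II and dendritic cell genes were higher for 12 of 14 (13 adjusted over the list alone, camera adjusted p = 4.39e-31), with adjusted p = 0.108 with an estimated correlation. The invariant chain gene Cd74 was higher by 8.17 ± 0.51 and H2-Ab1 by 7.45 ± 0.47. Late neutrophil genes were higher for 11 of 18 and lower for 1 (12 and 1 adjusted over the list alone, camera adjusted p = 7.21e-07), with adjusted p = 0.245 with an estimated correlation. The scavenger receptor gene Cd36 and the cathelicidin gene Camp, without counts in the 2 Dnmt3a Flt3 GMP libraries, were at least 11565-fold and 5898-fold higher. NF-kB and inflammatory genes were higher for 10 of 15 (10 adjusted over the list alone, camera adjusted p = 1.81e-07), with adjusted p = 0.135 with an estimated correlation, Zfp36, which encodes an mRNA decay factor, by 3.59 ± 0.23. The anti-apoptotic gene Mcl1 was higher by 3.87 ± 0.41.

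Mast cell, basophil and eosinophil genes were lower in Npm1 Flt3 GMP for 5 of 9 (6 adjusted over the list alone, camera adjusted p = 1.16e-08), with adjusted p = 0.135 with an estimated correlation, Mcpt8 by 3.77 ± 0.25 and Fcer1a by 5.20 ± 0.35. Cell cycle genes were lower for 12 of 24 and higher for 2 (16 and 2 adjusted over the list alone, camera adjusted p = 0.000687), with adjusted p = 0.313 with an estimated correlation. Mpo was lower by 1.30 ± 0.37 and Socs2 by 1.01 ± 0.19, and neither passed without Dnmt3a Flt3 GMP replicate 1 (adjusted p = 0.149 and 0.0820). Lower too were the lymphocyte kinase gene Lck by 4.59 ± 0.24 and the carbonic anhydrase gene Car2 by 4.37 ± 0.28. Mitochondrially encoded genes were higher for 7 of 8 (7 adjusted over the list alone, camera adjusted p = 3.91e-07), with adjusted p = 0.245 with an estimated correlation. In all, 3571 of 17200 genes differed, 2157 higher and 1414 lower. The number was 1098 without Dnmt3a Flt3 GMP replicate 1, 992 without replicate 3, 2127 with the replicate number of the titles as a block and 5403 with the library of conflicting labels taken by its title, where it shares an animal number with replicate 1.

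In LSK (4 and 2 libraries), Flt3 was higher in Npm1 Flt3 cells by 1.60 ± 0.29 (adjusted p = 0.00817), but did not pass without Dnmt3a Flt3 LSK replicate 2 (adjusted p = 0.0964) or with the library of conflicting labels by its title (adjusted p = 0.0581). Monocyte genes were higher for 14 of 16 (14 adjusted over the list alone, camera adjusted p = 1.75e-24) and MHC class II and dendritic cell genes for 13 of 14 (14 adjusted over the list alone, camera adjusted p = 1.15e-27), each with adjusted p = 0.179 with an estimated correlation. Ms4a6c was higher by 5.59 ± 0.47, Ly86 by 8.05 ± 0.72, H2-Aa by 4.42 ± 0.55 and Siglech, a surface lectin gene of plasmacytoid dendritic cells, by 7.14 ± 0.50. Primary granule genes were higher for 5 of 13 (6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00505), with adjusted p = 0.392 with an estimated correlation. Lymphoid genes were higher for 9 of 15 (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.44e-09), with adjusted p = 0.205 with an estimated correlation, the interleukin-7 receptor gene Il7r by 6.17 ± 0.77. With the library of conflicting labels by its title Il7r was higher by 3.11, which did not pass (adjusted p = 0.0788). Interferon response genes were higher for 12 of 21 (14 adjusted over the list alone, camera adjusted p = 1.43e-10), with adjusted p = 0.281 with an estimated correlation. The homeobox genes Hoxa9 and Hoxa7 were higher by 0.93 ± 0.25 and 1.37 ± 0.35, but did not pass without Dnmt3a Flt3 LSK replicate 2 (adjusted p = 0.260 and 0.172). The early response gene Egr1 was higher by 4.62 ± 0.59. Fos stood at 524 to 1427 CPM in Npm1 Flt3 LSK against 115 to 286 CPM in the 3 Dnmt3a Flt3 LSK libraries by title. In GMP its range was 1520 to 2924 against 47.3 to 78.9 CPM. Hspa1a overlapped in LSK (11.1 to 109 against 10.8 to 98.2 CPM) and in GMP (71.2 to 85.1 against 25.4 to 111 CPM). Whether handling of the samples gave the early response levels was not tested, and code series goes with genotype here. T and NK cell genes were higher for 3 of 9 (6 adjusted over the list alone, camera adjusted p = 0.00124) and mitochondrially encoded genes for 3 of 8 (5 adjusted over the list alone, camera adjusted p = 0.000809), with adjusted p = 0.205 and 0.433 with an estimated correlation. Cholesterol synthesis genes were lower for 6 of 15 (7 adjusted over the list alone, camera adjusted p = 0.00113), with adjusted p = 0.264 with an estimated correlation, and the apolipoprotein gene Apob was lower by 4.41 ± 0.32.

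In all, 2251 of 19470 genes differed in LSK, 1518 higher in Npm1 Flt3 and 733 lower. The number was 511 and 433 without Dnmt3a Flt3 LSK replicate 2 or 3, 1358 without Npm1 Flt3 LSK replicate 1, 4377 with DESeq2, 3496 with the stricter filter, 3396 with cell types by sample code, 3465 with the replicate number of the titles as a block and 3597 with the library of conflicting labels taken by its title, where it shares an animal number with replicate 2. The sexes of the animals go with the genotypes, since Xist was higher in Npm1 Flt3 LSK by 9.96 ± 0.57 and the Y-linked gene Ddx3y lower by 13.47 ± 0.67, so sex and genotype cannot be told apart.

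Within Npm1 Flt3 mice, LSK were compared with GMP (4 libraries each). Primary granule genes were lower in LSK for 9 of 13 (11 adjusted over the list alone, camera adjusted p = 4.4e-41 and 0.00473 with an estimated correlation). Hp was lower by 3.78 ± 0.23, the granule protease genes Prtn3 and Elane by 2.98 ± 0.22 and 5.24 ± 0.43, and Ms4a3 by 4.14 ± 0.33. Monocyte genes were lower for 10 of 16 (13 adjusted over the list alone, camera adjusted p = 2.54e-27 and 0.00473 with an estimated correlation), Ly6c2 by 3.88 ± 0.33 and the coagulation factor gene F13a1 by 4.69 ± 0.41. Lymphoid genes were higher for 9 of 15 (13 adjusted over the list alone, camera adjusted p = 1.3e-22 and 0.00473 with an estimated correlation), Lck by 4.76 ± 0.26 and Dntt by 7.39 ± 1.15, which did not pass with the animal number as a block (adjusted p = 0.0949). Stem cell genes were higher for 5 of 19 (8 adjusted over the list alone, camera adjusted p = 4.12e-10 and 0.00473 with an estimated correlation). Ly6a, the Sca-1 gene used in the sort, was higher by 5.23 ± 0.26 and the transcription factor gene Mecom by 3.16 ± 0.47. STAT5 targets were higher for 5 of 13 (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.98e-10 and 0.00473 with an estimated correlation), Socs2 by 2.34 ± 0.20 and Cish by 1.64 ± 0.21. Meis1 was higher by 2.14 ± 0.26, while Fcgr3, the Fc receptor gene used to sort GMP, was lower by 4.74 ± 0.27. Flt3 was higher by 0.37 ± 0.23, which did not pass (adjusted p = 0.429). In all, 980 of 21227 genes differed, 499 higher in LSK and 481 lower, 637 without Npm1 Flt3 GMP replicate 2, 652 without LSK replicate 2, 2090 with DESeq2, 642 with only the 2 groups in the fit and 1069 with the animal number as a block. Of these 1069 genes 635 were among the 980, and 32.9% of the 1069 were higher in LSK.

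Lineage-negative progenitors of Npm1 Flt3 mice given tamoxifen (TAM), which per the labels removes the mutant Flt3 allele through Cre, were compared with those given vehicle for 7 days (3 libraries each), to ask what changes when the mutation is lost. Flt3 stood at 121, 183 and 83.3 CPM in the TAM libraries and 209, 181 and 160 CPM in the vehicle libraries, and the counts do not separate the mutant allele from the other. The median gene was higher after TAM by 0.56 with TMM scaling and by 1.64 with library size alone. Falls of single genes are therefore named here only where they exceed 1.1, apart from mt-Co1 below. Counts of falling list members use the adjusted p alone. Flt3 fell by 1.68 ± 0.39 (adjusted p = 0.00126), with a value of -2.24 relative to the median gene. With library size alone its value was -0.50, which did not pass (adjusted p = 0.109). Nov fell by 7.57 ± 0.59, the interferon-induced membrane protein gene Ifitm1 by 7.21 ± 0.50, and Socs2 and Cish by 2.77 ± 0.41 and 2.88 ± 0.48. With library size alone the falls were 6.27 for Nov, 1.48 for Socs2 and 1.52 for Cish. The growth regulator gene Myc fell by 2.94 ± 0.41, Npm1 by 2.93 ± 0.40 and Hoxa9 by 2.00 ± 0.39. With library size alone these 3 were lower by 1.63, 1.63 and 0.73, with adjusted p = 0.0400 for Hoxa9. Hoxa7 and Hoxa10 did not pass with library size alone (adjusted p = 0.161 and 0.117).

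All 24 measured cell cycle genes fell after TAM (24 adjusted over the list alone, camera adjusted p = 6.28e-26), with adjusted p = 0.218 with an estimated correlation, and 23 fell with library size alone. Bub1, a spindle checkpoint gene, fell by 3.71 ± 0.43 and the DNA helicase gene Mcm7 by 3.20 ± 0.39, or by 2.40 and 1.95 with library size alone. Ribosome biogenesis genes fell for 15 of 15 (15 adjusted over the list alone, camera adjusted p = 1.02e-14), with adjusted p = 0.218 with an estimated correlation, and for 14 with library size alone. Glycolysis genes fell for 13 of 14 (13 adjusted over the list alone, camera adjusted p = 2.04e-11), with adjusted p = 0.218 with an estimated correlation, and for 10 with library size alone. Primary granule genes fell for 8 of 12 and rose for 1 (8 and 1 adjusted over the list alone, camera adjusted p = 1.27e-12), with adjusted p = 0.218 with an estimated correlation. Ms4a3 fell by 5.52 ± 0.48, Prtn3 by 5.06 ± 0.45 and Mpo by 4.78 ± 0.47. STAT5 targets fell for 4 of 12 and rose for 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0217), with adjusted p = 0.511 with an estimated correlation, but with library size alone 5 rose and 4 fell.

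Erythroid genes rose after TAM for 10 of 11 and fell for 1 (10 and 1 adjusted over the list alone, camera adjusted p = 3.74e-16), with adjusted p = 0.107 with an estimated correlation. Hba-a1 rose by 6.52 ± 0.47, or 5.95 relative to the median gene, Car2 by 6.55 ± 0.51 and the haem synthesis gene Alas2 by 4.15 ± 0.46. Interferon response genes rose for 19 of 21 and fell for 1 (19 and 1 adjusted over the list alone, camera adjusted p = 7.03e-16), with adjusted p = 0.218 with an estimated correlation, Irf7 by 4.99 ± 0.44 and Rtp4 by 6.35 ± 0.52. Late neutrophil genes rose for 13 of 18 and fell for 1 (13 and 1 adjusted over the list alone, camera adjusted p = 1.29e-10), with adjusted p = 0.218 with an estimated correlation, S100a8 by 4.34 ± 0.46. MHC class II and dendritic cell genes rose for 11 of 14 (11 adjusted over the list alone, camera adjusted p = 2e-06), with adjusted p = 0.218 with an estimated correlation. Stromal and endothelial genes rose for 8 of 10 with 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.00358), with adjusted p = 0.218 with an estimated correlation. T and NK cell genes rose for 5 of 10 (6 adjusted over the list alone, camera adjusted p = 6.52e-06), with adjusted p = 0.218 with an estimated correlation. Mitochondrially encoded genes fell for 4 of 8 (6 adjusted over the list alone, camera adjusted p = 0.0259), with adjusted p = 0.511 with an estimated correlation. With library size alone these 4 had changes of -0.14 (mt-Cytb), -0.04 (mt-Nd1), 0.08 (mt-Nd5) and 0.22 (mt-Co1), and none passed. Mitochondrial genes held 1.49% to 1.53% of counts in TAM and 1.11% to 1.77% in vehicle libraries, so this fall depends on the scaling. Genes of olfactory and vomeronasal receptors, which blood cells do not use, held 1362 to 2317 CPM in the TAM libraries and 123 to 610 CPM in the vehicle libraries. In all, 7926 of 25269 genes differed, 2544 higher and 5382 lower, with 81.5% of 11399 higher under library size alone and 5142 or 5159 genes without TAM replicate 1 or 3.

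**Figure D4:**
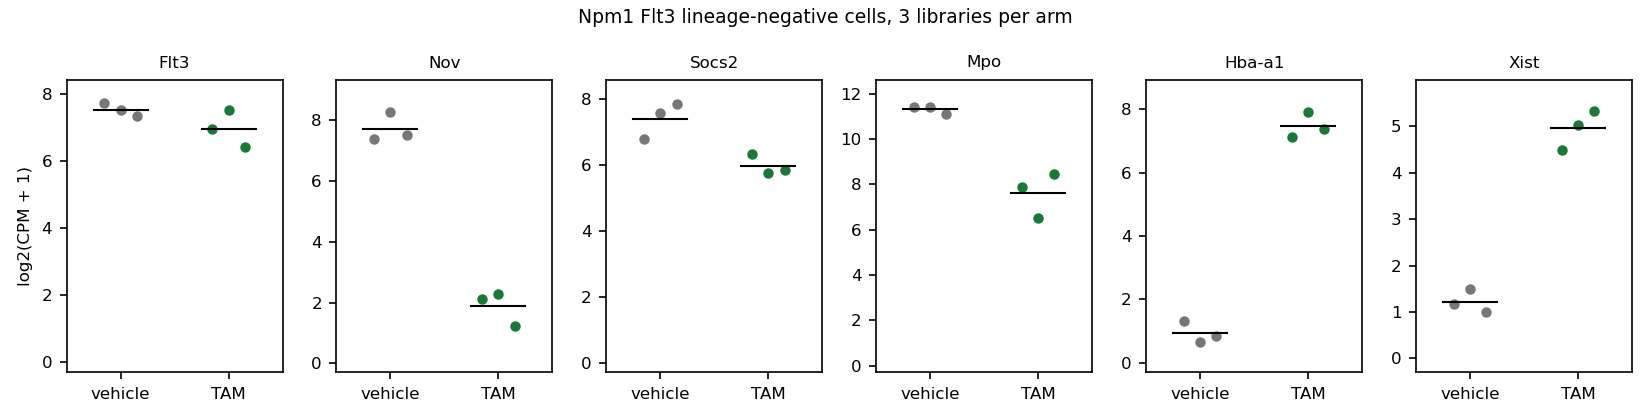
Each point is a library and each bar a group mean of log2(CPM + 1), scaled by library size alone, for Flt3, Nov, Socs2, Mpo, Hba-a1 and Xist in vehicle and TAM libraries of Npm1 Flt3 lineage-negative cells. All 3 TAM libraries lie below all 3 vehicle libraries for Nov, Socs2 and Mpo and above them for Hba-a1 and Xist.

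Genes that differed between Flt3 and WT cells were tested as sets in the TAM contrast, which uses other libraries. Camera ranked each set against all 25269 tested genes, of which 5382 fell and 2544 rose, with a median of 0.56. The sets hold only genes that passed the filter on low counts in Flt3 and WT libraries. Genes silent in blood cells, which held more CPM after TAM, can lift the other genes. No set was compared with other genes of like expression, so a low rank cannot be tied to loss of the allele. The genes higher in Flt3 LSK were lower after TAM than other genes (camera adjusted p = 2.36e-13), with adjusted p = 0.571 with an estimated correlation, and among 673 measured members 353 fell and 86 rose. The genes higher in Flt3 GMP were lower too (camera adjusted p = 9.78e-07), with adjusted p = 0.624 with an estimated correlation, and among 1185 members 415 fell and 114 rose. Genes lower in Flt3 GMP were also lower after TAM (camera adjusted p = 1.16e-41), with adjusted p = 0.478 with an estimated correlation, and among 1193 members 862 fell and 46 rose. The genes lower in Flt3 LSK did not pass (camera adjusted p = 0.194), with 212 lower and 125 higher of 788, and the 200 of them with the smallest p turned upwards (camera adjusted p = 0.0244), with adjusted p = 0.408 with an estimated correlation.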

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

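The test of the difference between cell types was planned, and the levels in the libraries left out were looked at after their labels were seen to conflict.

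The effect of the Flt3 mutation differed between LSK and GMP for 1278 genes by a test of the difference itself. None of the other 29 drawn splits, which shuffled week together with genotype, called a gene in that test.

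A single library stood apart from its group among 30 values tested for this, of marker genes, the mutated genes, depth, genes detected and shares of counts. Chance passes the cutoff for about 1 in 20 values, so 1 among 30 is no more than chance gives. Procr, a stem cell surface gene, stood at 0.785 CPM in Npm1 Flt3 GMP replicate 2 and at 0 to 0.0343 CPM in the other 3 libraries. No explanation was tested for it.

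The 2 Dnmt3a Flt3 libraries whose titles and sample codes name different cell types gave signal outside the comparisons. Mpo stood at 2607.5 CPM in the library with the title LSK replicate 1, against 2511 and 3212 CPM in the other Dnmt3a Flt3 LSK libraries. It stood at 41327 CPM in the library with the title GMP replicate 2, against 50230 and 52200 CPM in the other GMP libraries. Both values lie nearer to the group of the title than to that of the code.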

How the results depend on the processing

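The counts without the 2-week or the 8-week libraries and those of DESeq2 without the near-empty library were added after the data were seen, and the other settings given here with a moved value were planned. With DESeq2 the number of called genes went from 2393 to 912 in Flt3 GMP at all times, from 1364 to 366 at 4 weeks, from 258 to 442 for the LSK slope, from 1278 to 649 for the difference of effects, from 2251 to 4377 in Npm1 against Dnmt3a LSK and from 980 to 2090 in Npm1 LSK against GMP. Without the near-empty library DESeq2 called 2314, 1384 and 1445 for the GMP contrasts and the difference, so that library accounts for the low numbers. For the other counts moved by DESeq2 the cause was not tested.

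Without a filter on low counts the slopes gave 1830 genes in GMP and 653 in LSK, and the stricter filter gave 3496 in Npm1 against Dnmt3a LSK. A block on replicate numbers gave 120 for the LSK slope, and 3465 and 2127 in Npm1 against Dnmt3a LSK and GMP. For the LSK slope, 8 against 2 weeks gave 905 and any difference among the 4 times 995. Without the 2-week libraries the slopes gave 52 in GMP and 1 in LSK, with fewer samples, and without the 8-week libraries 673 in LSK. At 4 weeks only, with fewer samples, the difference of effects gave 424. The conflicting libraries taken by title gave 3597 in LSK and 5403 in GMP, counting 2 libraries with 1 animal number as replicates in each, and by code 3396 in LSK. With only the 2 groups in the fit, Npm1 LSK against GMP gave 642. Apart from the settings with fewer samples, the cause was not tested.

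In the TAM contrast, genes higher in Flt3 LSK had adjusted p = 0.571 with an estimated correlation, those higher in Flt3 GMP 0.624 and those lower in Flt3 GMP 0.478. Fry, which tests a set against no change and not against other genes, gave 0.0669, 0.127 and 0.0279. The genes lower in Flt3 LSK turned upwards for the 200 with the smallest p (adjusted p = 0.0244, 0.408 with an estimated correlation and 0.0478 with fry), and the cause was not tested.

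Leaving out 1 library at a time gave 1557 to 2569 genes in Flt3 GMP and 1049 to 1596 in Flt3 LSK at all times, and 770 to 1492 and 715 to 1173 at 4 weeks. The slopes gave 611 to 1261 in GMP and 59 to 505 in LSK, and the difference of effects 659 to 1400. WT LSK against GMP gave 2305 to 3144, Npm1 LSK against GMP 637 to 1257 and TAM 5142 to 9876. Npm1 against Dnmt3a gave 433 to 2554 in LSK and 992 to 3523 in GMP, where a lone Dnmt3a library is assumed to vary like the other group.

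Of the values of named genes under these settings 3601 kept their direction and side of the threshold, 73 no longer passed, 2 newly passed and 6 turned. Without the 2-week libraries the slopes turned to 0.0125 for Flt3 in GMP, and in LSK to 0.10 for Hspa1a, 0.45 for Igj and 0.27 for Igkc, none of which passed. Leaving out 1 library at a time, the slope of Flt3 in LSK ran from -0.0165 to 0.00597, turned without Flt3 8-week LSK replicate 1, and it was 0.0321 without all 3 8-week libraries. The cause was not tested. Depth limits the low genes of the WT and Flt3 libraries, the smallest of which holds 306571 counts apart from the near-empty one.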

Other observations

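All tests of explanations in this part, and the splits of the samples, were chosen after the results were seen.

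Cholesterol synthesis genes rose in Flt3 cells, for 5 of 13 in GMP (5 adjusted over the list alone, camera adjusted p = 0.0189) and 6 of 13 in LSK (7 adjusted over the list alone, camera adjusted p = 0.00161), with adjusted p = 0.314 and 0.239 with an estimated correlation. Genes of the p53 response rose for 3 of 9 in LSK (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00491 and 0.0451 with an estimated correlation). They rose in GMP too, for 3 of 7 (4 adjusted over the list alone, camera adjusted p = 0.00522), with adjusted p = 0.0690 with an estimated correlation. Glycolysis genes fell for 5 of 13 in GMP and rose for 1 (5 and 1 adjusted over the list alone, camera adjusted p = 0.027), with adjusted p = 0.194 with an estimated correlation.

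Other splits of the same libraries into groups of the same sizes were fitted. For Flt3 against WT over all times, 1 of 60 drawn splits, the real one, gave as many genes in GMP (2393, highest other 114). In LSK it was also 1 of 60 (1480, highest other 26), and for the difference of effects 1 of 30 (1278, highest other 0). These draws shuffled week together with genotype, so differences between weeks went into the spread of the shuffled fits. Low numbers in those fits therefore cannot exclude chance for genotype alone. For the slope in LSK only the weeks were shuffled, and 1 of 60 orders gave as many (258, highest other 16), so chance can be excluded at that level. For Npm1 LSK against GMP (980, highest other 0, 1 of 35 splits), 3 pairs of libraries share an animal, and the 8 splits that part these pairs as the real one does are too few for a share under 0.05. For the slope in GMP 1 of 60 orders gave as many, but the highest other gave 1025 against 1075. With 10 splits, too few for a share under 0.05, the real split and the highest other gave 1364 and 0 in GMP and 1003 and 0 in LSK at 4 weeks, 3041 and 0 in WT LSK against GMP, and 7926 and 0 for TAM, with 1 split each as large.

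The slopes over weeks rest in large part on the 2-week libraries: without them the median slope of the called genes was 30.4% of its size in GMP and 36.4% in LSK, against 134% and 124% without the 8-week libraries. Without the 2-week libraries 835 of 1075 genes in GMP and 227 of 258 in LSK kept their direction. RNA from plasma cells may be a source of the immunoglobulin reads in LSK at 2 weeks: of 9 measured plasma cell markers, 6 had all 2-week libraries above all later ones, with Igj, an immunoglobulin chain gene like Ighm in the same list, at 5444 to 15030 CPM, although sorting for Kit and Sca-1 should remove such cells. Derl3 stood at 23.1 to 97.9 CPM against at most 6.52 CPM later, while Fkbp11, Irf4 and Prdm1 overlapped. Fos, Egr1 and Hspa1a lay above all later libraries in 6 of 6 pairs of gene and cell type, which handling or stress could give. No label of batch or day separates that from the labelled week. A change between 2 and 4 weeks in the mutant mice stays open, as no WT mice were sampled at 2 weeks.

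After TAM, genes silent in blood cells held at least 2.23 times the CPM of any vehicle library, so their rises are consistent with background reads. Xist reads per 100 reads on those genes numbered 0.923, 2.32 and 1.86 in TAM against 0.207, 1.47 and 0.224 in vehicle, so the libraries overlap but 2 of 3 TAM libraries lie above every vehicle library, and whether background gives the Xist reads stays open. Of the 5382 falling genes 2105, or 39.1%, also fell with library size alone, which argues against TMM scaling as the whole source. The remaining falls depend on the scaling. Background reads are part of the library size, so they can lower the share of other genes under that scaling too. The test therefore does not separate background from a fall in the cells. Total counts were 15053592 to 22654054 in the TAM libraries and 40865360 to 103446979 in the vehicle libraries. Loss of the mutant allele and other effects of TAM cannot be told apart, as no mice without the allele were given TAM.

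Monocyte genes were higher in Npm1 Flt3 than in Dnmt3a Flt3 LSK, and GMP among the sorted LSK would bring granule genes too. Of 13 granule genes 5 were higher, too few or too many to decide. The animals' sex and code series go with the genotype, since 0 Dnmt3a libraries had Xist above 10 CPM, as all sorted Npm1 libraries had. These cannot be told apart from an effect of the second mutation, which stays open and untested.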
